A study of Mus musculus with 2 samples.

How the data were processed

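H3K27ac was profiled in 2 chromatin immunoprecipitation libraries from embryonic mouse midbrain, 1 for each biological replicate, which the labels describe as separate pools of 120 and 88 embryos. The analysis started from 4 deposited peak lists in the narrowPeak layout on the mm10 assembly, per the labels. These were a list for each replicate, a list from both replicates pooled, and a replicated set that the accompanying text files derive from the pooled list and both replicate lists. The aligner, the peak caller, its versions and thresholds, and the criterion of the replicated set were not given in the sources used here. The pooled and replicated lists are therefore not independent of the replicate lists.

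Each peak carries values that the authors deposited. The score is a whole number that the authors deposited for each peak, and it was not used because its scaling was not given in the sources used here. The fold enrichment, a ratio of the fragment pileup at the summit to the expected background, is the authors' own value for each peak. The deposited −log10 p-value and −log10 q-value come from the authors' peak calling. That column 7 is a fold enrichment was worked out from the values. For peaks with −log10 p under 250, fold and p were solved together for the pileup, and 100% came out whole within 0.05. The fold was taken there as a ratio with 1 added to the pileup and to the background. The commonest background was 2.89 and 2.83 fragments in the lists of replicates 1 and 2 and 5.56 in the pooled list. With the added 1, a fold of at least 4 is not an equal limit in lists of different background. Many peaks in the deposited lists are weak. The share with q over 0.05 was 13.9% in replicate 1, 17.1% in replicate 2, 5.21% in the pooled list and 0.234% in the replicated set. Fold enrichment was used only to describe, rank or filter peaks within a list, since a deeper or purer library gives other values at the same locus.

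All computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9. Genes and sequence came from GENCODE release M21 on GRCm38 (patch 6), the assembly that mm10 names, with 21853 protein-coding genes. Peaks on chromosomes 1 to 19, X and Y entered the comparisons. Coordinates are 1-based. Overlap needed at least 1 bp, and its background was the mean over 100 shuffles of peak positions along their chromosomes outside gaps. A promoter peak lay within 1000 bp of any TSS of a protein-coding transcript, and all other peaks were distal and given to the nearest such TSS. The promoter fold of a gene is the highest fold among peaks that overlap such a window. Only the peak had to overlap it, so the summit may lie outside. Domains joined peaks less than 10 kb apart.

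The 20 gene lists, the 19 motifs and the tests were fixed before the data were examined. Each list's marked share was tested against all other protein-coding genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists. It was also set against 10000 random lists of the same size matched on promoter CpG count, counted within 500 bp of the TSS. Distal peaks per gene were compared with 10000 random lists matched on decile of territory length, the stretch of genome nearer to a gene than to any other. Motif matches on both strands were counted in distal peaks and in flanks of the same length free of pooled peaks, and up to 100 shuffles of the letters gave the background. Only motifs with at least 40 distinct shuffles (16 of 19) were counted as above or below, a minimum added after the first motif table was seen. The erythroid gene Ahsp was not found under that symbol in the annotation and was left out.

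The rule for named genes was fixed beforehand as well. For each list it took the up to 4 members with the highest promoter fold, the first 4 members without a promoter peak in alphabetical order, and the 2 members with the most distal peaks. It also took the genes in the 20 widest domains and at the 10 widest peaks, and list genes with a promoter peak in 1 replicate's list alone. The microRNA genes, symbol families and other genes named only in the closing section were chosen after their values were seen.

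The list tests were tested on simulated data over 21853 genes. Of 100 random lists of 15 genes, 2 were called by Fisher's exact test and 1 against CpG-matched lists. Of 100 CpG-rich lists with no effect, 77 were called by Fisher's test and 1 against CpG-matched lists, so the Fisher result alone cannot separate a list from its CpG content. All 100 lists simulated at a marked share of 5% were called by Fisher's test. For distal peaks, all 40 lists with doubled peak numbers and 0 of 40 unchanged lists were called. The simulated counts spread far less than the real ones, which reached 134 at Zfhx3, so the power in real lists may be lower.

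With 2 replicates, values are given as a mean and SD with no test that has libraries as its units. The closing section compares the 2 replicates within gene lists, with genes as units, which describes these 2 libraries only. Proportions carry 95% Wilson or exact binomial intervals that cover counting error only. Alternatives were other promoter windows (500 and 2500 bp), a fold of at least 4, a −log10 q of at least 5, an overlap of 50% of the peak, lists of equal length, pooled peaks, 1 TSS per gene, other joining distances (5 and 20 kb), the region within 200 bp of summits, unmasked bases only, a limit of 100 kb on distal peaks, and each replicate alone.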

Results

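H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the midbrain of mouse embryos at 12.5 days of development. The midbrain at this age holds dividing neural progenitors and newly formed neurons. There was 1 group with 2 biological replicates, each a pool of male and female embryos of the strain B6NCrl. Replicate 1 was made from 120 embryos and replicate 2 from 88. The design held no second tissue, age or treatment, so the comparisons were between the replicates, between parts of the genome and between lists of genes. The deposited peak lists held 95899 peaks for replicate 1, 92883 for replicate 2, 104303 for both replicates pooled and 52608 in the authors' replicated set. The median peak had 13 fragments piled up at its summit in each replicate's list, 20 in the pooled list and 27 in the replicated set. Total read numbers were not given in the sources used here, so the depth of each library is unknown beyond these pileups.

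The first comparison asked how far the peaks of the 2 pools coincided. The tallest peaks lay at the same loci in both, among them the promoters of Ywhaz and Actb, which encode a ubiquitous adaptor protein and cytoplasmic actin. The authors' fold enrichment at Ywhaz was 42.4 in replicate 1 and 48.6 in replicate 2, and at Actb 43.0 and 40.5. Tall peaks were also shared at neural progenitor genes. At Msi1, which encodes an RNA-binding protein of neural stem cells, fold enrichment was 27.5 and 42.4. At Sox2, a transcription factor that maintains neural progenitors, it was 30.1 and 17.7. Each value is the highest fold among peaks overlapping the promoter window, so the summits in the 2 lists may differ. Weak peaks often appeared in a single list. Of the 20 gene lists described below, 31 genes carried a promoter peak in 1 replicate's list alone. In replicate 1 alone these were Helt, Pitx3, Slc18a3, Dlx5, Foxg1, Rax, Tbr1, Vax1, Hoxc13, Foxc2, Prrx2, Tbx18, Eng, Flt1, Pecam1, Sox18, Irf8, Hba-x, Myf6 and Hhip, with a median fold of 3.03. In replicate 2 alone they were Pdgfrb, Twist2, Emcn, Erg, C1qa, Epb42, Klf1, Slc4a1, Cebpa, Chrna1 and Myh3, with a median fold of 3.12.

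By an overlap of at least 1 bp, 54.1% of the peaks of replicate 1 met a peak of replicate 2 (95% Wilson interval 53.8 to 54.4%). In the other direction 54.5% did (54.2 to 54.8%), a mean of 54.3%. These are 2 directions of 1 comparison, so they give no spread between replicates. Peaks shuffled along their chromosomes overlapped in 3.56% and 3.61% of cases. In the top decile of fold enrichment 100% of peaks overlapped in both directions, and in decile 8 the shares were 82.4% and 82.9%. In decile 2 they were lowest, at 23.9% and 24.5%, and in decile 1 they were 30.3% and 30.9%. Of the bases covered by either list, 47.6% were covered by both. Intervals cover counting error only.

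**Figure D1:**
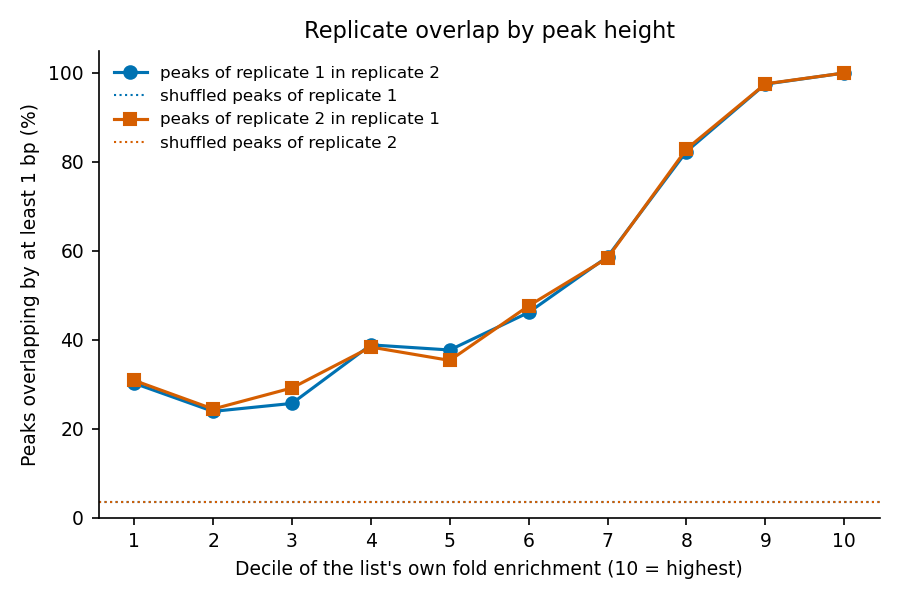
Share of peaks overlapping a peak of the other replicate by at least 1 bp (percent) against the decile of the list's own fold enrichment, where decile 10 is the highest. Circles show replicate 1, squares replicate 2 and dotted lines shuffled peaks, and the shares were 30.3% and 30.9% in decile 1, 23.9% and 24.5% in decile 2 and 100% in decile 10.

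The second comparison asked which pooled peaks the authors kept as replicated. The replicated set, which included the promoter peaks of Ywhaz, Axin2 and Sox2, held 50.4% of the pooled peaks (95% Wilson interval 50.1 to 50.7%). Among pooled peaks with a fold enrichment of at least 4, 99.8% were kept. The kept peaks were wider and taller than the dropped ones, with a median width of 595 bp and fold of 3.96, against 214 bp and 2.59. All 43482 pooled peaks that shared at least 50% of their own length, or of the replicate peak's length, with peaks of both replicates were kept. A further 9117 kept peaks, 17.3% of the set, did not meet that criterion, and 335 kept peaks overlapped no peak of either replicate. These 9117 had a median fold of 3.05 and a median width of 336 bp. Other rules were tried as well. Coverage of at least 50% of the pooled peak by both replicates' peaks, the planned rule, was met by 67.6% of kept peaks and 1 dropped peak. An overlap of 1 bp with both was met by 83.3% of kept and 736 dropped peaks. The rule given first is thus the one that no dropped peak met. The authors' own criterion was not given in the sources used here, and the replicate peaks behind it may differ from the deposited lists.

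The third comparison divided H3K27ac between promoters and distal regions. Of the replicated peaks, 27.1% (14255 peaks, 95% Wilson interval 26.7 to 27.5%) lay within 1 kb of a transcription start site (TSS) of a protein-coding gene. For shuffled peaks this share was 3.69%. The other 38344 peaks were distal. Introns outside promoters held 40.02% of replicated peaks and intergenic sequence 29.6%, against 36.6% and 57.3% of shuffled peaks. Coding exons held 1.61% and untranslated exons 1.63%, against 1.16% and 1.28%. Promoter peaks were wider and taller than distal ones, with a median width of 891 bp and fold of 7.52, against 532 bp and 3.64. The median distal peak lay 35.5 kb from the nearest protein-coding TSS, and 75.7% lay within 100 kb.

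A replicated promoter peak marked 11499 of 21853 protein-coding genes (52.6%). The lists of the separate replicates marked 12058.5 ± 0.707 genes (SD, n = 2), and 11363 genes were marked in both. The promoter share was lower in the replicates' own lists, at 19.2% ± 0.127 (SD, n = 2). It was 43.9% among replicated peaks with a fold enrichment of at least 4 and 17.8% among pooled peaks.

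The fourth comparison asked which groups of genes carried H3K27ac at their promoters. Every member of the neural progenitor list (20 of 20) and of the pan-neuronal list (20 of 20) was marked. Among progenitor genes the tallest promoter peaks belonged to Msi1 (fold enrichment 35.7), the Notch ligand Dll1 (35.1), Sox2 (33.1) and the Notch effector Hes5 (32.6). These folds come from the replicated set, and in the separate lists of replicates 1 and 2 Dll1 had 32.6 and 19.9 and Sox2 30.1 and 17.7, so that their place among the tallest was not kept in replicate 2. Each fold belongs to a peak that overlaps the promoter window, and in a wide peak the summit may lie outside that window. The peak over the Sox2 promoter spanned positions 34647915 to 34652152 of chromosome 3 (GRCm38). The tallest pan-neuronal peaks lay at Myt1l (30.8), Tagln3 (30.7), Scrt1 (30.0) and Nhlh2 (26.1), of which Myt1l, Scrt1 and Nhlh2 encode transcription factors of new neurons. Both lists exceeded the share of 52.6% among all other genes (adjusted p = 1.97e-05 for each, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 20 lists). Cell cycle genes (15 of 15) and housekeeping genes (15 of 15) were marked throughout (adjusted p = 0.000263 for each by the exact test). Their tallest peaks lay at E2f1 (15.5), Ccnd1 (12.7), Cdk4 (12.5) and Ccna2 (8.99), and at Ywhaz (51.8), Actb (48.0), Tubb5 (32.0) and Eef1a1 (30.6).

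Genes that pattern the midbrain and the isthmus, the signalling boundary to the hindbrain, were marked in 16 of 20 cases (80%, exact 95% interval 56.3 to 94.3%, adjusted p = 0.0255 by Fisher's exact test). The tallest peaks belonged to Mab21l2 (25.5), to Otx2 (23.3) and Otx1 (21.9), homeobox genes of the forebrain and midbrain, and to En2 (19.1), a homeobox gene of the midbrain and hindbrain. The Otx2 peak covered positions 48664514 to 48672502 of chromosome 14, and the En2 peak positions 28165603 to 28170533 of chromosome 5. The members without a replicated promoter peak were the secreted isthmus signals Fgf8 and Wnt1 and the transcription factor genes Helt and Pax2. In the lists of replicates 1 and 2, 18 and 17 of the 20 members were marked, and 18 with pooled peaks, so not all of these lacked a peak there. Targets of signalling pathways were marked in 15 of 18 cases (83.3%, adjusted p = 0.0179 by the exact test). Axin2, a target of Wnt signalling, had a fold of 39.6. Spry2, an antagonist of receptor tyrosine kinases, had 38.9, the hedgehog receptor gene Ptch1 32.2 and Nrarp 31.9, while Bmp4, Heyl and Hhip were not marked. The folds of Nrarp in the separate lists were lower, at 13.9 and 14.5, and Otx2 had 13.7 in replicate 1 and 20.7 in replicate 2. Peaks of the separate lists can have other summits, so these folds need not be heights at the same position.

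The dopaminergic lineage list, covering neurons that arise in the ventral midbrain, was marked in 10 of 18 cases (55.6%, adjusted p = 0.862 by Fisher's exact test). Neurog2 (16.8), Wnt5a (8.53), Foxa1 (7.77) and Foxa2 (7.47) had the tallest peaks, and Aldh1a1, Corin, Drd2 and Ferd3l were among those without. Neurotransmitter genes were marked in 5 of 15 cases (33.3%, adjusted p = 0.26 by the exact test). They included the glutamate transporter gene Slc17a6 (23.2), the GABA-synthesis genes Gad2 (12.8) and Gad1 (8.09), and the GABA transporter gene Slc32a1 (10.4), but not Chat, Dbh, Fev or Phox2a. Forebrain patterning genes were marked in 12 of 20 cases (adjusted p = 0.819 by the exact test), led by Bcl11b (22.6), Lhx2 (17.0), Emx2 (12.7) and Six3 (8.20). Arx, Eomes, Gsx2 and Hesx1 were not marked. Bcl11b had a fold of 24.0 in replicate 1 and 14.7 in replicate 2. The forebrain list held 15 marked genes in replicate 1 and 10 in replicate 2. Hindbrain and cerebellar genes were marked in 6 of 10 cases (adjusted p = 0.862 by the exact test), with Zic4 (19.1), Lhx9 (17.3), Mafb (15.7) and Barhl1 (6.55) marked and Atoh1, Egr2, Ptf1a and Tlx3 not.

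None of the 39 Hox genes, which pattern the hindbrain and trunk, had a replicated promoter peak (exact 95% upper bound 9.03%, adjusted p = 4.29e-12 by Fisher's exact test). Hox genes lie side by side in clusters, so their promoters are not independent. The bound and the p-value treat them as independent and so overstate the evidence. The unmarked genes Hoxa1, Hoxa10, Hoxa11 and Hoxa13 come first by name. In the separate lists 1 Hox promoter was marked in replicate 1, that of Hoxc13, and 0 in replicate 2.

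The liver, erythroid, skeletal muscle, microglia, heart and endothelial lists were marked less often than other genes by Fisher's exact test, without CpG matching. None of 14 liver genes was marked, Afp, Alb, Apoa1 and Apoa2 among them (adjusted p = 0.000143 by Fisher's exact test). In the erythroid list 1 of 15 genes was marked (adjusted p = 0.000871 by the exact test), namely Nfe2 (3.42), while Alas2, Epb42, Epor and Gata1 were not. In the skeletal muscle list 1 of 13 was marked (adjusted p = 0.00292 by the exact test), the myosin light chain gene Mylpf (10.5), but not Acta1, Chrna1, Chrng or Ckm. The microglia and macrophage list had 2 of 15 (adjusted p = 0.00655 by the exact test), C1qb (3.89) and Csf1r (2.73), without Aif1, C1qa, C1qc and Cx3cr1. The heart list had 3 of 15 (adjusted p = 0.0283 by the exact test), Myh7 (15.9), Ryr2 (7.77) and Nppa (6.71), without Actc1, Gata4, Gata6 and Hand2. In replicates 1 and 2 the fold was 3.71 and 8.10 at Ryr2 and 5.29 and 4.01 at Nppa. The endothelial list had 3 of 14 (adjusted p = 0.0444 by the exact test), Egfl7 (3.80), Kdr (3.51) and Esam (2.90), without Cdh5, Cldn5, Emcn and Eng. Marked endothelial genes made up 35.7% of the list without replicate 1 and 50% without replicate 2, and neither share passed the test. The heart share was 26.7% without replicate 1 and likewise without replicate 2, and the erythroid share was 26.7% without replicate 1, none of which passed. Without replicates 1 and 2 in turn, skeletal muscle genes were marked in 23.1% and 15.4% of cases, liver genes in 14.3% and 7.14%, and microglia genes in 20% both times, and these calls were kept. Without replicate 2 the erythroid share was 13.3%. The heart list also did not pass with a window of 2500 bp (26.7%) or with 1 TSS per gene (20%). With pooled peaks the shares were 57.1% for endothelial genes, 26.7% each for microglia, erythroid and heart genes, 23.1% for skeletal muscle genes and 83.3% for signalling targets, and none of these 6 lists passed. With a fold of at least 4 the signalling (61.1%) and heart (20%) lists did not pass, and later glia (7.69%) did.

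Later glial genes (3 of 13, adjusted p = 0.0692), neural crest and sensory ganglion genes (7 of 12, adjusted p = 0.862) and genes of mesenchyme and meninges (8 of 15, adjusted p = 1.0) did not pass the exact test. The glial share was 46.2% without replicate 1 and likewise without replicate 2. Marked members were Mbp (4.72), Pdgfra (3.81) and Cnp (3.15) among glial genes and Pou4f1 (13.6), Tfap2a (11.4), Ntrk2 (10.7) and Ntrk3 (8.53) among crest genes. In mesenchyme, Foxc1 (6.10), Twist1 (5.94), Prrx1 (4.27) and Foxd1 (3.70) led. In replicates 1 and 2 the fold was 10.8 and 8.17 at Pou4f1, 6.78 and 12.02 at Tfap2a, 5.65 and 7.55 at Ntrk3, 3.84 and 5.75 at Twist1, and 3.34 and 2.56 at Prrx1. Unmarked were Aldh1l1, Aqp4, Gfap and Mag, then Erbb3, Foxd3, Ntrk1 and Prph, then Col1a2, Col3a1, Foxc2 and Lum.

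CpG-rich promoters tended to carry H3K27ac more often, so each list was also set against 10000 random lists matched on promoter CpG count, a permutation of the genes within CpG strata. Pan-neuronal genes stayed above (100% against a median of 60%, adjusted permutation p = 0.002), as did progenitor genes (100% against 80%, adjusted permutation p = 0.02). The Hox genes stayed below (0 of 39 against a median of 71.8%, adjusted permutation p = 0.002). The pan-neuronal and Hox values rest on the smallest p that the random lists can give, 0.0002. Liver, endothelial and neurotransmitter genes were at the threshold with an adjusted p of 0.05 each, against medians of 21.4%, 50% and 66.7%. Midbrain and isthmus genes equalled their matched median of 80% (adjusted permutation p = 1.0), and signalling targets theirs of 83.3% (adjusted p = 1.0). The heart, skeletal muscle, microglia, erythroid, cell cycle and housekeeping lists no longer passed either, with adjusted p from 0.110 to 0.963. Genes are not replicates, so all of these tests describe the 2 libraries. The random lists draw single genes from across the genome, so they do not account for the clustering of the Hox genes.

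**Figure D2:**
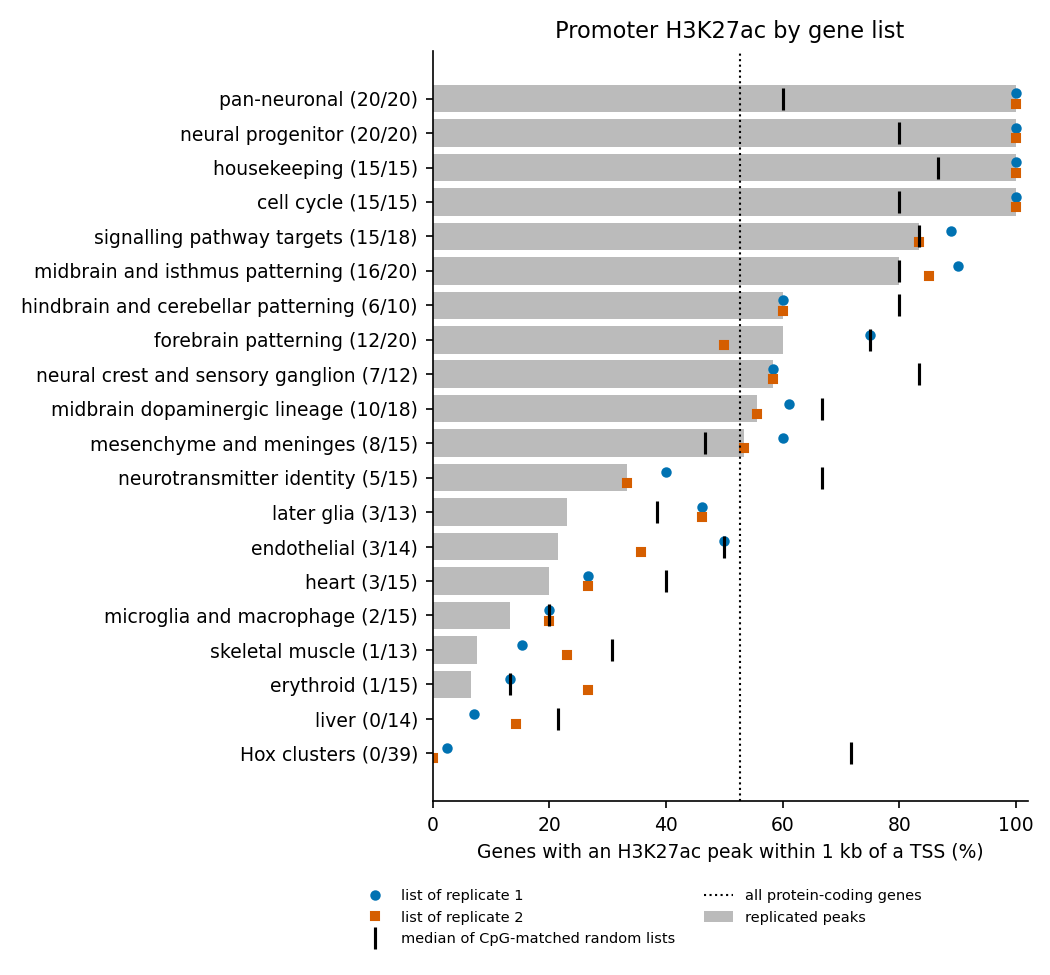
Share of the genes of each list with an H3K27ac peak within 1 kb of a TSS (percent), for replicated peaks (bars) and for the lists of replicate 1 (circles) and replicate 2 (squares). Vertical ticks mark the median of CpG-matched random lists and the dotted line all protein-coding genes (52.6%), and the bars run from 0 of 39 Hox genes to 20 of 20 pan-neuronal genes.

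Distal peaks, assigned to the nearest protein-coding TSS, exceeded matched lists in the progenitor, midbrain and isthmus, and pan-neuronal lists. The progenitor list held 15.2 distal peaks per gene against a median of 2.95 in random lists matched on territory length (adjusted permutation p = 0.004, from 0.0002, the smallest p that 10000 lists can give). Msi2, which encodes an RNA-binding protein related to Msi1, had 110 and Sox2 had 48. Midbrain and isthmus genes held 12.5 against 3.65 (adjusted permutation p = 0.034), led by Lmx1b with 36 and Meis2 with 28. Pan-neuronal genes held 10.9 against 3.45 (adjusted permutation p = 0.0373), led by Myt1l with 48 and Rbfox3 with 41. No other list passed the same test. Neural crest and sensory ganglion genes held 4.75 against 2.375 and did not pass (permutation p = 0.27), so a large difference in means need not pass. From a single replicate's longer list the means were higher, at 24.2 without replicate 1 and 26.7 without replicate 2 for progenitor genes, 20.7 and 19.6 for midbrain and isthmus genes, and 20.8 and 19.4 for pan-neuronal genes, and the calls were kept. The 39 Hox genes together had 3 distal peaks, all near Hoxa1 (adjusted permutation p = 0.194). Their adjusted p passed the threshold when either replicate was left out, at means of 0.180 peaks per gene without replicate 1 and 0.154 without replicate 2.

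Other lists had single members with many distal peaks, counted here in the replicated set. The longer lists of replicates 1 and 2 gave other counts, with 49 and 48 at Bcl11b and 36 and 33 at Six3. Ptprc, without a promoter peak, had 24, Mki67 27, Bcl11b 30, Axin2 23, Ntrk2 21, Lmx1a 19, Six3 and Lef1 18 each, Slc17a6 and Zic4 17 each, and Ddc and Barhl1 14 each. Mbp and Ccnd1 had 12 each, Slc32a1 and Pou4f1 11 each, Cps1 10 and Dcn 9. The other members named for distal peaks had 7 or fewer, namely Foxc1, Kdr, Emcn, Aqp4, Ly86, Alas2, Gypa, Tat, Ryr2, Tbx5, Tnnt3, Myh3, Ywhaz and Eef1a1.

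The fifth comparison ranked the widest H3K27ac domains, made by joining replicated peaks less than 10 kb apart and ordered by the bases under peaks. The widest lay over Msi2 on chromosome 11 (positions 88329779 to 88730116), with 176 peaks covering 219 kb. The next lay over Gse1 and Gins2 on chromosome 8 (120250446 to 120590173, 170 kb) and over Zmiz1 on chromosome 14 (25455416 to 25665578, 101 kb). A domain with 1700001O22Rik and Ntmt1 on chromosome 2 covered 86.1 kb. A domain on chromosome 10 covered 79.6 kb and held Efna2, Cirbp, Midn, Dazap1, Cbarp, Atp5d, Gamt, Ndufs7, Mum1 and 1600002K03Rik. Further domains lay over Ephb2 (73.5 kb), which encodes an ephrin receptor, Srgap3 (72.4 kb), Bahcc1 (60.6 kb), the kinase gene Src (53.2 kb), the corepressor gene Ncor2 (48.1 kb), Igdcc3 and Parp16 (47.3 kb) and Cxxc5 (44.8 kb). The orphan nuclear receptor genes Nr2f2 and Nr2f1 lay in domains of 44.2 kb and 42.1 kb. Myo18a, Sez6, Pipox and Gm10277 shared a domain of 42.6 kb, and Zmynd8 and Msi1 lay in domains of 41.3 kb and 39.2 kb. The remaining 3 of the 20 widest domains held no protein-coding TSS and lay on chromosomes 12, 7 and 3.

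Of these 20 domains, 17 overlapped a top 20 domain from the peaks of replicate 1 alone and 15 from those of replicate 2 alone. All 20 overlapped a top 100 domain of each replicate. The 20 domains held 3.06% of all bases under replicated peaks, among 24823 domains of which 14036 were single peaks. With pooled peaks, or with replicated peaks of a fold of at least 4, 13 of the 20 stayed in the top 20. The widest single peak covered 17.2 kb on chromosome 7 (79496125 to 79513321), and another of 15.8 kb followed it at 79513446 to 79529284. Both were nearest to the coding gene Polg. The first was 17.3 kb wide in replicate 1, but in replicate 2 it fell into 3 peaks of which the widest covered 8.35 kb. The peak over the Msi1 promoter covered 16.0 kb and a peak beside Sox2 15.4 kb. Peaks over the promoters of Zfhx3 (15.03 kb), Tnrc18 (13.4 kb), Otx1 (13.1 kb), Lhx2 (12.2 kb) and Kdm6b (12.2 kb) and a peak nearest to 1700001O22Rik (11.97 kb) completed the 10 widest. Several of these were broken up in the separate lists. The widest peak there in replicates 1 and 2 was 3.42 and 4.63 kb at Lhx2, 6.80 and 7.52 kb at Otx1, 7.94 and 7.25 kb beside Sox2, 7.80 and 14.2 kb at Zfhx3, 7.02 and 13.1 kb at Tnrc18, and 7.62 and 11.1 kb at Kdm6b.

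**Figure D3:**
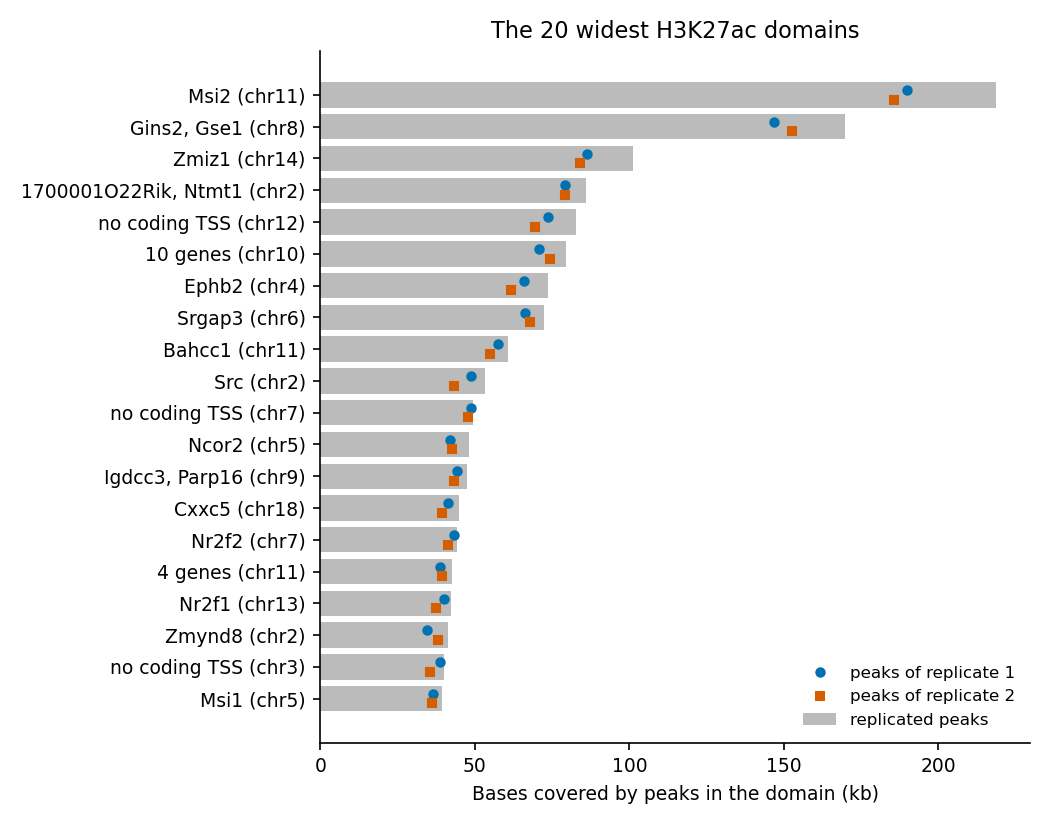
Bases covered by peaks (kb) in the 20 widest H3K27ac domains, with bars for replicated peaks, circles for peaks of replicate 1 and squares for peaks of replicate 2 in the same domain. Coverage ran from 219 kb at Msi2 to 39.2 kb at Msi1.

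The sixth comparison asked which transcription factor motifs were dense in distal peaks relative to their flanks. The SOX motif ACAAWG, bound by the Sox family to which Sox2 belongs, had a peak to flank ratio of 1.11, against a median of 0.946 for shuffled versions of the motif. In the separate lists it was 1.08 ± 0.00235 (SD, n = 2). The octamer ATGCAAAT of POU factors had a ratio of 1.14 against 0.770 (replicates 0.999 ± 0.0631, n = 2). The MEF2 motif CTAWWWWTAG had 0.837 against 0.640 (replicates 0.847 ± 0.000935, n = 2), so that it was less dense in peaks than in flanks but less depleted than its shuffled versions. The motif of the insulator protein CTCF was less dense in peaks than in flanks, at a ratio of 0.624 against 1.80 (replicates 0.579 ± 0.0882, n = 2), from 264 matches. This motif holds no CG pair, but shuffles of its letters can. The SP-KLF, NRF1, CRE and ETS motifs, which hold CG pairs, had ratios of 1.215 to 2.16. The shuffles keep base composition but not CG pairs, so the distance from 1.80 cannot be read as depletion of CTCF alone. The E-box CAGCTG, bound by neurogenic bHLH factors, had 1.73 against 1.35 and lay at percentile 96.0 of its shuffles, inside the central 95%.

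The OTX motif TAATCC (0.837 against 0.808) and the other E-box CATCTG (1.15 against 1.07) also lay inside, as did the RFX, NFI, ETS, AP-1, CRE, HNF4, TEAD, REST and NRF1 motifs. The GATA motif AGATAA had a ratio of 0.798 against a median of 0.747 for its 29 shuffles. The homeodomain motif TAATTA had a ratio of 0.718, above all 13 of its shuffles, and the SP-KLF motif 2.16, above all 6. Shuffles this few cannot define the outer 2.5%, so a minimum of 40 was required. That minimum was set after the first motif table had been seen, and without it 5 motifs rather than 3 would count as above. In the list of replicate 2 alone the POU, MEF2 and CTCF motifs lay at percentiles 95, 97 and 3.09, so these 3 calls were lost without replicate 1. In the list of replicate 1 alone the TEAD motif lay at percentile 99, so it counted as above without replicate 2. The CTCF call was also lost at a fold of at least 4, where its ratio was 0.815. Distal peaks had a GC content of 49.7% and flanks of 44.8%.

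**Figure D4:**
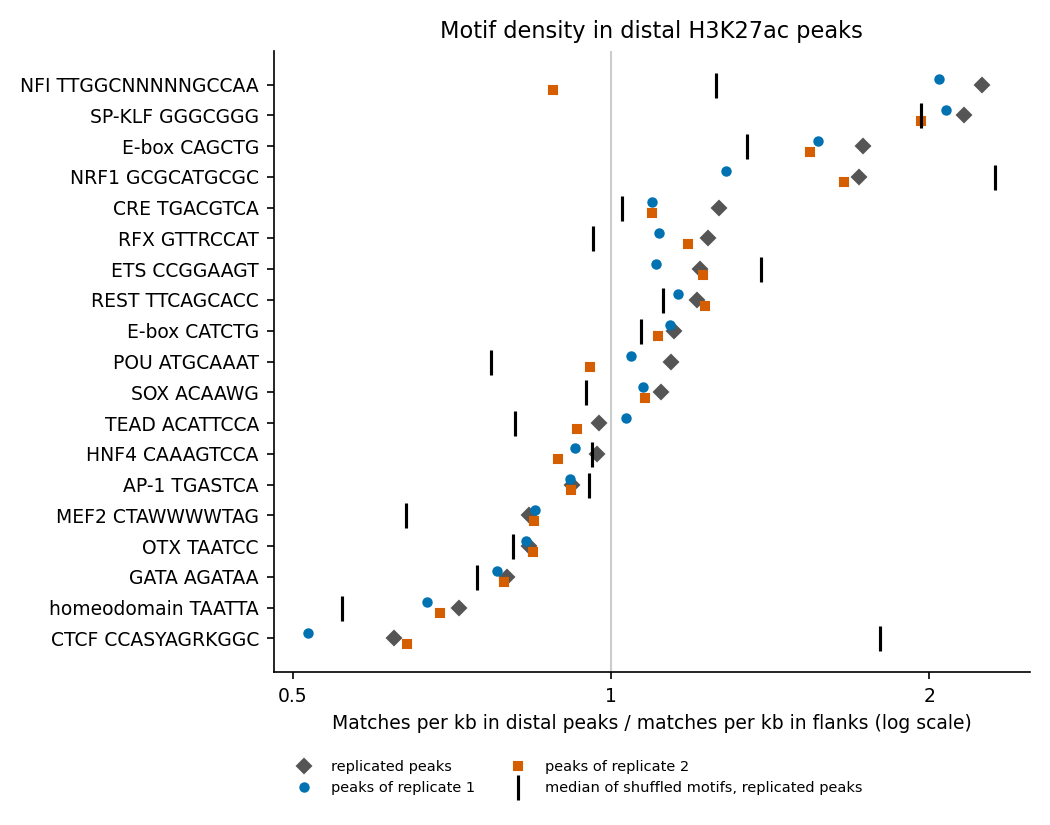
Matches per kb in distal peaks divided by matches per kb in flanks (log scale) for 19 motifs, in replicated peaks (diamonds) and in the peaks of replicate 1 (circles) and replicate 2 (squares). Vertical ticks mark the median of shuffled motifs in replicated peaks, and the CTCF ratio of 0.624 lay far left of its tick at 1.80. The CTCF motif holds no CG pair, which its shuffles can hold.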

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

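Both counts in this part were chosen after the data were examined, and no test was run on them. In sequence outside the assembled chromosomes, which no comparison used, 9 replicated peaks were listed, and they are given as a count with no background. They ranged in fold enrichment from 1.62 to 41.0, and the tallest lay on a scaffold placed on chromosome 4.

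Among distal replicated peaks, 9.58% (3673 peaks) lay within 1000 bp of the start of a transcript that is not protein-coding, and these starts did not enter the promoter comparison. The share for shuffled distal peaks was 6.48%.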

How the results depend on the processing

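Of 70 values that answer a comparison, 40 stayed within a tolerance and 30 moved beyond it, and the cause was not tested for any. The tolerance was a factor of 1.5 for counts, and for shares the spread between replicates or the 95% interval. For shares it was narrow, at 0.127 percentage points for the promoter share and the counting interval for the others. Even small changes in a share thus counted as moved, so the count of 30 does not measure their size. The minimum number of motif shuffles was chosen after the motif table was seen, and all other alternatives were fixed before the data were examined. Replicate overlap for replicates 1 and 2 was 45.1% and 44.8% at 50% of the peak, 75.8% and 77.1% at a fold of at least 4, 79.3% and 80.4% at a −log10 q of at least 5, and 55.2% and 54.0% with lists of equal length. The fold and q limits were applied to both lists, so a peak counted as unshared when its partner fell under the limit. Against the full list of replicate 2, deciles 8, 9 and 10 of replicate 1 (fold of 3.92 and above) overlapped in 82.4%, 97.5% and 100% of cases. The share of pooled peaks kept was 99.8% at a fold of at least 4, and 42.7% of pooled peaks met a peak of both replicates by 1 bp. The promoter share was 25.4% and 31.2% in windows of 500 and 2500 bp, 43.9% at a fold of at least 4, 17.8% with pooled peaks, 22.9% with 1 TSS per gene, and 19.1 to 19.3% without a replicate. Gene lists below at promoters fell from 7 to 2 with pooled peaks, to 4 against CpG-matched lists, and to 4 to 5 without a replicate. Of the 4 lists against CpG-matched lists, Hox had an adjusted permutation p of 0.002 and liver, endothelial and neurotransmitter genes were at the threshold with 0.05 each, the last not among the 7. The lists above fell from 6 to 2 against CpG-matched lists. Lists below at distal peaks rose from 0 to 1 with pooled peaks and to 1 without either replicate. Of the widest domains, 13 stayed in the top 20 with pooled peaks and 13 at a fold of at least 4. Motifs below the shuffles fell from 1 (CTCF) to 0 at a fold of at least 4 and to 0 to 1 without a replicate, and motifs above ranged from 1 to 4 without a replicate and reached 5 with no minimum number of shuffles. Among 160 values for separate promoter lists, 135 kept their call, 22 lost it and 2 gained it. In 1 more, the endothelial list with pooled peaks, the call was also lost, at 57.1% against 57.0% of all genes marked by pooled peaks. Of 120 values for distal lists 117 kept their call and 3, all of the Hox list, gained it, and of 95 ratios of separate motifs 26 moved by less than 1 SD and 69 by more. These SDs rest on n = 2 and ranged from 0.00017 (CRE) to 0.822 (NFI), so the motif counts do not measure how far ratios moved. The median summit held 13 fragments per replicate, and the effect of depth was not tested.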

Other observations

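The symbol families, the microRNA genes and all tests in this part were chosen after the data were examined, except that the bounds for the X pileup and for shared promoters were set before their results were seen. Among 271 families of genes that share a symbol stem, with at least 10 genes each, 18 fell below random lists matched on promoter CpG and 6 lay above (Benjamini-Hochberg adjusted p under the 0.05 threshold). Against all other genes by Fisher's exact test, without CpG matching, 67 fell below and 85 lay above, and the Wnt, Fgf and Bmp families named next did not pass (adjusted p = 0.157, 0.193 and 0.123). Among the families below, Wnt genes were marked in 6 of 19 cases (31.6% against a matched median of 79.0%, adjusted permutation p = 0.00542) and Fgf genes in 8 of 22 (36.4% against 68.2%, adjusted p = 0.02). Bmp genes were marked in 3 of 12 cases (25% against 66.7%, adjusted permutation p = 0.0181) and Tbx genes in 2 of 13 (15.4% against 61.5%, adjusted p = 0.00542). None of 14 serotonin receptor genes (Htr, adjusted permutation p = 0.00542) or 12 alpha protocadherin genes (Pcdha, adjusted p = 0.00834) was marked, against a matched median of 50% for each. The Pcdha genes also lie in a cluster, so their promoters are not independent. Zinc finger genes of the Zfp family were marked in 287 of 394 cases (72.8% against 57.9%, adjusted permutation p = 0.00542) and Zbtb genes in 40 of 41 (97.6% against 82.9%, adjusted p = 0.0181). The values of 0.00542 rest on 0.0002, the smallest p that the random lists can give.

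The 3 genes of the neural microRNA miR-9 lay in wide domains, a description with no test of enrichment: Mir9-3 in the domain ranked 11 (chromosome 7, 79496125 to 79558537, 49.5 kb under peaks), Mir9-1 in that ranked 19 (chromosome 3, 88196979 to 88242877, 39.98 kb) and Mir9-2 in that ranked 52 (29.7 kb). The domain on chromosome 12 without a coding TSS (117149313 to 117291378, 82.6 kb) held Mir153. In the replicated set the largest number of distal peaks near any gene was 134 at Zfhx3, followed by 113 at Rapgef5, 110 at Msi2, 108 at Gse1 and 107 at Zfp608. The longer lists of replicates 1 and 2 gave 221 and 208 at Zfhx3, 186 and 154 at Rapgef5, 183 and 167 at Msi2, 188 and 176 at Gse1, and 168 and 154 at Zfp608. The order after Zfhx3 was thus not kept.

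Dlx5, Foxg1, Rax, Tbr1 and Vax1, 5 forebrain patterning genes, had a promoter peak in replicate 1 alone and 0 in replicate 2 alone (exact binomial p = 0.0625, adjusted p = 0.75), and 15 of the 20 forebrain genes had more distal peaks in replicate 1 against 2 in replicate 2. Pan-neuronal genes leaned the other way (4 against 13, percentile 1.78, permutation p = 0.038, adjusted p = 0.38), as did dopaminergic genes (3 against 10, adjusted permutation p = 0.461). Midbrain and isthmus genes held 19.55 and 20.7 distal peaks per gene in replicates 1 and 2 (9 against 10 genes, percentile 4.2, permutation p = 0.0878, adjusted p = 0.4). Progenitor genes lay at percentile 97.2 (permutation p = 0.059, adjusted p = 0.393). The longer list of replicate 1 is argued against, since all other genes gave 0.994 genes marked in replicate 1 alone for each in replicate 2 alone. The distal excess (11.6 against 9.05 peaks per gene) lay at percentile 99.5 of random lists matched on the number of distal peaks, with a permutation p = 0.01 and an adjusted p of 0.2, and at percentile 98.7 without Nkx2-1. An earlier version matched on territory length gave percentile 99.9 and an adjusted permutation p of 0.018, with the same adjusted p for the progenitor list, and was replaced after its result was seen because its random lists held fewer peaks, and the bounds for chance were then rewritten. More forebrain tissue in the pool of replicate 1 is a candidate explanation that the adjusted p of 0.2 leaves undecided against chance at the calling threshold, and with 1 pool on each side the pools cannot be told apart from their libraries.

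The X chromosome held 5.41 replicated peaks per Mb against 16.1 to 35.1 on the autosomes. Gene density alone is argued against, since peaks per gene were 0.374 times those on autosomes (0.934 against 2.5), and distal peaks per gene were 0.485 against a median of 2.94 in 1000 autosomal lists matched on territory length. Promoter CpG content as the whole cause is argued against, with 35.9% of X genes marked against 39.8% in CpG-matched autosomal lists (percentile 0.06, permutation p = 0.0016), where the bound was first set as below all random lists and was relaxed to the central 95% after the result was seen. With 1 active X copy per cell, signal may be lower, and the upper quartile of the pileup at CpG-rich X promoters was 0.748 times that of matched autosomal promoters, with a bootstrap interval of 0.676 to 0.849 that spans the bound of 0.75. Thinning autosomal pileups to 0.75, near the measured ratio, left 0.801 of the pooled autosomal peaks and thinning to 0.5 left 0.355. The X to autosome ratio of pooled peaks per Mb was 0.177, which also carries any difference in genes per Mb, so it is not a like measure. Per gene the ratio was 0.374, but in replicated peaks, so it is not a like measure either. It was not computed for pooled peaks. The X chromosome held 1244 pooled peaks for 948 genes. Autosomes with fewer genes all held more, from 2801 on chromosome 19 (715 genes) to 4822 on chromosome 12 (642 genes). These counts argue against a drop to 0.75 as the whole cause, since that drop left 0.801 of the peaks. Whether a drop to 0.5 would be enough is undecided, and no other biological explanation was tested.

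Of 86 genes in the endothelial, microglia, erythroid, liver, heart and skeletal muscle lists, 10 were marked (Egfl7, Esam, Kdr, C1qb, Csf1r, Nfe2, Myh7, Nppa, Ryr2 and Mylpf). Only Mylpf, beside Tbc1d10b, shared its peak with the promoter of another protein-coding gene. For the other marked members this argues against such a promoter as the cause, while starts of non-coding transcripts were not examined. The share, 1 of the 10 against 22.1% of other marked genes (Fisher's exact p = 0.702), met the bound set beforehand, at or below that of other marked genes. With 10 genes, however, the test cannot separate these shares. Cells of these types in the pools could give such peaks, and distal peaks per marked gene lay at percentile 36.3 of matched marked genes (1.70 against 2.20). The bound against this explanation was first a percentile under 50, which this value met, and was lowered to 2.5 after the result was seen because a value so near the median of lists of 10 genes lies within their spread, so the explanation stays open. Among marked genes of the endothelial, microglia and erythroid lists the peaks were weak, with fold enrichment from 2.73 to 3.89.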
